A study of Mus musculus with 13 samples.

How the data were processed

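The series holds 13 arrays of colorectal tissue from mice in which 1 Apc allele is deleted in cells that express a Cdx2-driven Cre recombinase, a model of spontaneous colorectal tumors. Per the labels, mice received miR-200c, miR-302 family members and miR-369 strands, or a negative control microRNA, carried by carbonate apatite particles, in 24 tail vein injections at 3 per week from 8 weeks of age, with 25 µg of each microRNA. Tissue was divided into normal and tumor tissue. The arrays fall into 4 groups by their titles: normal tissue of microRNA-treated mice (2 arrays), tumors of microRNA-treated mice (2 arrays), normal tissue of control mice (2 arrays) and tumors of control mice (7 arrays). The labels of the control arrays name the negative control only in their description field, and no label says which mouse gave which sample. It was assumed that all control mice received the negative control on the same schedule.

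Per the labels, 35 ng of total RNA per sample was labelled with Cy3 and hybridized to a mouse expression array read in 1 colour. Per the file headers, the authors extracted the images with Feature Extraction 10.7.3.1, and the deposited values of each array are fluorescence intensity on a linear scale, background-subtracted and detrended within the array but not scaled between arrays. The deposited table of the whole series held the same intensity values, with a largest relative difference of 0 from the processed signal of each array. The mean raw intensity and the local background intensity of each spot, also deposited, were used for 1 alternative only.

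Control spots (3671) were left out, which left 59305 spots of 55681 different probes. Spots that the extraction software marked as non-uniform or as population outliers were set to missing before spots of the same probe were averaged, and 54 probes then lacked a value on some array. The log2 processed signal of each array was reduced by the log2 of its 75th percentile, so every level below is a log2 difference from that percentile. A probe was kept if its signal was well above background on at least 2 of the 13 arrays (35214 probes), and each gene was represented by its probe with the highest mean over all arrays. This gave 25486 genes or transcripts, of which 16670 had a symbol in the reference table supplied with the data. Probe coordinates are those printed in the files, on the mm9 assembly, and no genome sequence was used here.

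Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 (tables read with version 1.17.8 of data.table), on all 13 arrays with 1 shared estimate of the spread, and Benjamini-Hochberg adjusted p-values under 0.05 were called. An additive model of tissue and treatment gave the tumor effect over both groups of mice and the microRNA effect over both tissues. A model of 4 group means gave the tumor effect in each group of mice, the microRNA effect in each tissue and the difference between the tumor effects. A total of 32 gene lists of pathways, cell types and reported microRNA targets was tested in each of the 7 contrasts, adjusted over the lists. The test called camera below was limma's cameraPR on the t-statistics of eBayes, at a preset correlation of 0.01. The lists were tested again on the log2 values with limma's camera function at an estimated correlation, and with fry. The procedure was tested on simulated data with known changes in all 7 contrasts, with independent noise and no slide or shared animal. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

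The groups, contrasts, filters, gene lists, most alternatives and the rule for naming genes were set before the data were examined. That rule takes, for each contrast, up to 10 genes with the largest rise and up to 10 with the largest fall among called genes with an official symbol and no overlap between the groups, up to 4 members of each described list with the smallest p, and a fixed set of Wnt, proliferation and microRNA target genes. For the difference between the tumor effects the no-overlap condition was dropped, and where fewer than 3 genes passed in a direction, the 3 with the smallest unadjusted p were taken as values that did not pass. The text names a part of the genes the rule took, chosen after their values were seen; some are not reported here. Where a gene was not well above background on any array of the lower group, its fold change is printed as a lower limit ("at least"). For the difference between the tumor effects the fitted value is printed, also for genes near background in some groups.

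The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited table without scaling between arrays, no filter on dim probes, a filter by group, the mean of all probes of a gene, a fit to the compared groups alone, eBayes with trend and robust estimation, an added 2-fold threshold, the slide as a block, each slide alone, the number in the array's file name as a random block, the replicate number as a block, and each array left out in turn. Leaving out control tumors 1 and 5 and leaving out control normal 2 and control tumor 3 were added after the data were seen, as was the estimated correlation under 9 of the other settings in 2 contrasts. No sample was left out of the fits reported first. Tests of microRNA seed matches in 3′ untranslated regions were not run because they need sequence that was not supplied.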

Results

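Gene expression was measured on 13 arrays, 1 per sample: 2 of normal tissue and 2 of tumors from mice given the microRNA combination, and 2 of normal tissue and 7 of tumors from mice given the control microRNA. Between 50.7% and 57.0% of the probes were well above background on each array, and the 75th percentile of the processed signal ran from 214 to 740. It was 214 to 320 on the 4 normal arrays and 415 to 740 on the 9 tumors, so the intensity of an array went with its tissue. The balance of rises and falls between tumors and normal tissue depends on scaling this difference out. The arrays came from 2 slides, with 8 arrays on slide 1 and 5 on slide 2, and both arrays of control normal tissue were on slide 2. The first principal component held 48.7% of the variance and placed the 4 normal arrays, at -118.83 to -105.87, apart from the 9 tumors, at -18.38 to 123.62. The second held 16.1% and placed every array of slide 2 (12.68 to 99.93) above every array of slide 1 (-58.72 to -6.96). No label says which animal gave which sample, so p-values measure the spread between samples only, and several tumors may share an animal. In the file names, control tumors 1 and 2 carry the number 5, control tumor 3 carries 10 and control tumors 4 to 7 carry 6. Control normals 1 and 2 carry 9 and 10. Normal and tumor arrays of microRNA mice carry 8 for replicate 1 and 2 for replicate 2. If this number marks the animal, which no label states, the 7 control tumors come from fewer mice.

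**Figure D1:**
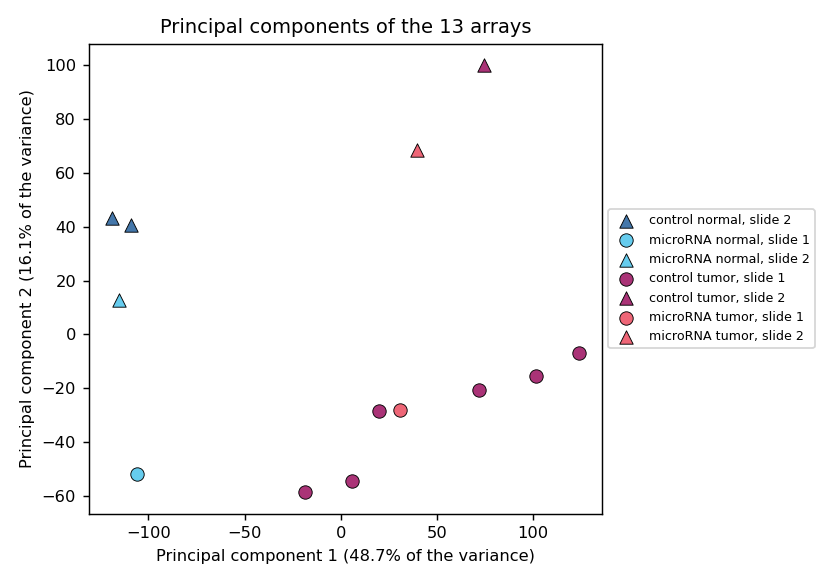
First against second principal component of the 13 arrays, calculated on those of the 25486 genes or transcripts with a value on every array, with circles for slide 1, triangles for slide 2. Normal and tumor arrays lie apart on the first axis (48.7% of the variance), and the slides lie apart on the second (16.1%).

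The first question was which genes distinguished tumors from normal tissue over both groups of mice. Tumors held far higher levels of the stromelysin Mmp10, a secreted protease that degrades extracellular matrix, at 3.93 ± 0.73 (SD, n = 9) against -3.60 ± 1.59 (SD, n = 4), a log2 difference of 7.70 (SE 0.59, limma adjusted p = 3e-05). The probe of Mmp10 (NM_019471) lies on chromosome 9 from 7510011 to 7510070 on mm9. The neutrophil chemokines Cxcl1 (log2 5.99) and Cxcl5 (5.79), the cytokine Il11 (5.94), the Wnt ligand Wnt10a (6.08) and the transcription factor Onecut2 (6.17) rose as well, and the secreted phosphoprotein Spp1 was at least 45.1-fold higher. The adipocyte serine protease Cfd had the largest fall among named genes (-8.72), and the carbonic anhydrase Car3 (-6.74), the resistin-like gene Retnla (-6.02) and the glucuronosyltransferase Ugt2b5 (-7.15) fell with it. In all, 7994 of 25486 genes changed, with 2979 higher and 5015 lower in tumors.

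Wnt target genes rose as a group, which is the pathway that Apc restrains. Of 22 measured members, 19 rose, none fell and 3 were not called, with 19 also rising when adjusted over the list alone (median log2 2.36, camera adjusted p = 3.53e-18, and adjusted p = 0.313 with an estimated correlation). The secreted Wnt inhibitors Dkk2 and Wif1 rose by log2 5.22 and 5.34, the feedback regulator Nkd1 by 3.76 and the transcription factor Prox1 by 4.68, while Axin2 rose by 2.51, Myc by 1.32 and Ccnd1 by 0.77. Cd44 differed by 0.42 (adjusted p = 0.196), and Apc itself by 0.02 (adjusted p = 0.943), with a probe that cannot show the loss of function of 1 allele. Among 12 crypt stem cell markers, 4 rose and 2 fell, or 5 and 3 when adjusted over the list alone (median 0.40, adjusted p = 0.0336, and 0.338 as adjusted p with an estimated correlation). Smoc2 (2.22), Lgr5 (2.52) and Ascl2 (1.40) rose. Proliferation genes were higher in all 24 measured members, of which 17 rose, or 20 adjusted over the list alone (median 0.75, adjusted p = 1.08e-08, and adjusted p = 0.338 with an estimated correlation). Top2a rose by 1.36, Bub1b by 1.27 and Mki67 by 0.60.

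Inflammation genes showed the strongest list result: 16 of 19 members rose, none fell, and 17 rose when adjusted over the list alone (median 3.52, adjusted p = 1.3e-31, and adjusted p = 0.161 with an estimated correlation). The interleukin Il1b rose by log2 3.91 and the monocyte chemokine Ccl2 by 3.44. Neutrophil markers rose in 7 of 9 members, all 7 also when adjusted over the list alone (median 2.41, adjusted p = 8.92e-11, and adjusted p = 0.196 with an estimated correlation). The calprotectin subunits S100a8 (5.19) and S100a9 (4.92) and the gelatinase Mmp9 (4.16) rose. S100a8 and S100a9 are members of both of these lists. Macrophage and dendritic cell markers had 3 members up and 1 down of 15, the same numbers when adjusted over the list alone (median 0.59, adjusted p = 0.00534, and 0.338 as adjusted p with an estimated correlation). The endotoxin receptor Cd14 rose by 1.61 and the antigen presentation gene H2-Aa fell by 1.87. Mast cell markers rose in 4 of 8 members and fell in 1, or 6 and 1 when adjusted over the list alone (median 1.58, adjusted p = 0.0336, and adjusted p = 0.338 with an estimated correlation). The mast cell protease Mcpt2 rose by 1.95. Lymphocyte markers went the other way. T and NK cell markers fell in 11 of 16 members, or 12 adjusted over the list alone (median -1.32, adjusted p = 0.000848, and adjusted p = 0.338 with an estimated correlation), with Cd3d at -1.90 and Cd8b1 at least 4.01-fold lower. B cell markers fell in 4 of 11 members, or 9 adjusted over the list alone (median -1.84, adjusted p = 0.0363, and adjusted p = 0.585 with an estimated correlation), with Cd79b at -2.46.

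Tumors had lower levels of genes of differentiated epithelium. Mature colonocyte genes fell in 16 of 22 members, or 17 adjusted over the list alone (median -2.36, adjusted p = 8.54e-05, and adjusted p = 0.356 with an estimated correlation). The sulfotransferase Sult1a1 fell by 4.24 and the carbonic anhydrase Car4 by 1.69. Enteroendocrine genes fell in 9 of 13 members, or 11 adjusted over the list alone (median -2.03, adjusted p = 0.000848, and adjusted p = 0.338 with an estimated correlation). Sct and Sst, which encode the hormones secretin and somatostatin, fell by 4.63 and 3.29. Goblet cell genes fell in 3 of 17 members, or 7 adjusted over the list alone (median -1.16, adjusted p = 0.046, and adjusted p = 0.585 with an estimated correlation). Ang4 fell by 2.61, Clca1 by 3.14 and Tff3 by 1.26, while the mucin Muc2 differed by -1.16 (adjusted p = 0.263). The intestinal transcription factor Cdx2, whose promoter drives the recombinase in this model, fell by 3.12. Paneth cell genes split: of 6 members, the matrilysin Mmp7 (5.08) and the phospholipase Pla2g2a (3.75) rose and the pentraxin Mptx1 fell (-5.43). The list had 3 members up and 1 down when adjusted over the list alone (median 1.85, adjusted p = 0.00949, and adjusted p = 0.361 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 15 members, or 15 adjusted over the list alone (median -0.87, adjusted p = 5.13e-06, and adjusted p = 0.338 with an estimated correlation), with Cox4i1 at -1.34 and Atp5o at -1.17. Without scaling between arrays the median of this list turned to 0.13, against an all-gene median of 0.89. The all-gene median was -0.11 with the scaling used.

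Markers of the outer gut wall and its surroundings were lower in tumors than in normal tissue. All 13 smooth muscle markers fell, also when adjusted over the list alone (median -2.67, adjusted p = 9.57e-06, and adjusted p = 0.338 with an estimated correlation). The smooth muscle actin Actg2 fell by 2.67, the filament gene Synm by 3.28 and the myosin kinase Mylk by 2.25. All 9 adipocyte markers fell, also when adjusted over the list alone (median -4.61, adjusted p = 3.83e-10, and adjusted p = 0.313 with an estimated correlation). Adipoq, the gene of the fat hormone adiponectin, fell by 6.16. Enteric neuron and glia markers fell in 8 of 14 members, or 9 adjusted over the list alone (median -1.52, adjusted p = 0.00107, and adjusted p = 0.338 with an estimated correlation), with Sox10 at -1.27 and Uchl1 at -2.35. Small intestine genes fell in 10 of 11 members, the same number when adjusted over the list alone (median -3.69, adjusted p = 1.64e-05, and adjusted p = 0.338 with an estimated correlation), with Fabp1 at -3.55 and Apoc3 at -4.08. Their mean level went from -1.66 to -3.66 in control mice and from 2.48 to -3.83 in microRNA mice. Without adjustment for treatment, the 2 probes of Apoc3 gave -4.44 and -0.20. Fibroblast markers rose in 4 of 13 members, also 4 when adjusted over the list alone (median 0.14, adjusted p = 0.0175, and adjusted p = 0.475 with an estimated correlation). Their mean level rose in microRNA mice only, from 1.77 in normal tissue to 2.78 in tumors. In control mice it was 2.39 in normal tissue and 2.32 in tumors, and the list was not called there (median -0.16, camera adjusted p = 0.489). The collagen genes Col1a1 (2.29) and Col1a2 (1.43) rose. Mesenchymal transition genes rose in 5 of 14 members and fell in 1, or 6 and 1 when adjusted over the list alone (median 0.77, adjusted p = 0.000848, and adjusted p = 0.338 with an estimated correlation). The matrix genes Fn1 and Sparc rose by 1.98 and 1.15, whereas the transition factors Zeb1 (-0.28, adjusted p = 0.467) and Zeb2 (-0.43, adjusted p = 0.231) were not called.

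The other 12 lists were not called in this contrast. Interferon-stimulated genes (median -0.67, adjusted p = 0.0525) had 6 of 21 members down, with Irf7 at -2.48, and pluripotency genes (-0.81, adjusted p = 0.095) had 1 up and 4 down of 9. Reported miR-200c targets (-0.32, adjusted p = 0.998), reported miR-302 targets (-0.06, adjusted p = 0.998) and epithelial junction and keratin genes (-0.26, adjusted p = 0.998) were far from the threshold. Plasma cell markers (-0.42, adjusted p = 0.741), endothelial markers (0.13, adjusted p = 0.26) and squamous epithelium markers (-0.49, adjusted p = 0.219) did not pass. Neither did distal Hox genes (-0.66, adjusted p = 0.639), glycolysis and hypoxia genes (-0.22, adjusted p = 0.465), p53 target genes (0.19, adjusted p = 0.696) and immediate early and heat shock genes (0.39, adjusted p = 0.257). The median and the mean of the epithelial junction list differed in sign. The cell cycle inhibitor Cdkn1a, a member of 2 lists, fell by 1.03 on its brightest probe, but another of its 3 probes gave 0.60.

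With the slide as a block 8437 genes changed between tumors and normal tissue, and within slide 2 alone 4894 did, and within slide 1 alone 10 did. Slide 1 held no control normal array, so its value rests on 1 tumor and 1 normal array of microRNA mice and is no value over both groups. Of the 20 lists called, 18 were called with the slide as a block, 12 within slide 1, 19 within slide 2 and 16 without microRNA normal 2. Wnt target genes had medians of 2.36, 2.03 and 2.63 in the 3 fits by slide, inflammation genes 3.72, 2.62 and 4.08, adipocyte markers -4.90, -3.73 and -5.34, and smooth muscle markers -2.56, -1.34 and -2.67. B cell markers stood at 0.34 and Mptx1 at 0.44 within slide 1, that is in microRNA mice alone, and camera called a difference between the tumor effects of the 2 groups of mice for B cell markers (median 3.32, adjusted p = 9.76e-08, and adjusted p = 0.277 with an estimated correlation), with no member called over all genes. The share of changed genes that rose was 37.3%, against 51.7% with quantile normalization, 50.8% with median scaling and 20.8% with normexp correction, 95.5% without scaling between arrays and 23.96% without a filter. Goblet cell genes and B cell markers were no longer called without control normal 1 (medians -1.29 and -1.33), control normal 2 (-0.97 and -1.69), control tumor 1 (-1.28 and -1.86) or control tumor 3 (-0.94 and -1.78). Without microRNA normal 2 the calls ended for goblet cell genes (-1.25), crypt stem cell markers (0.25), mast cell markers (1.43) and fibroblast markers (0.05), and without microRNA tumor 1 for fibroblast markers (-0.03). Leaving out control normal 2 gave 3842 genes, leaving out control normal 1 gave 4663, and leaving out both arrays with Xist signal, control normal 2 and control tumor 3, gave 4150.

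**Figure D2:**
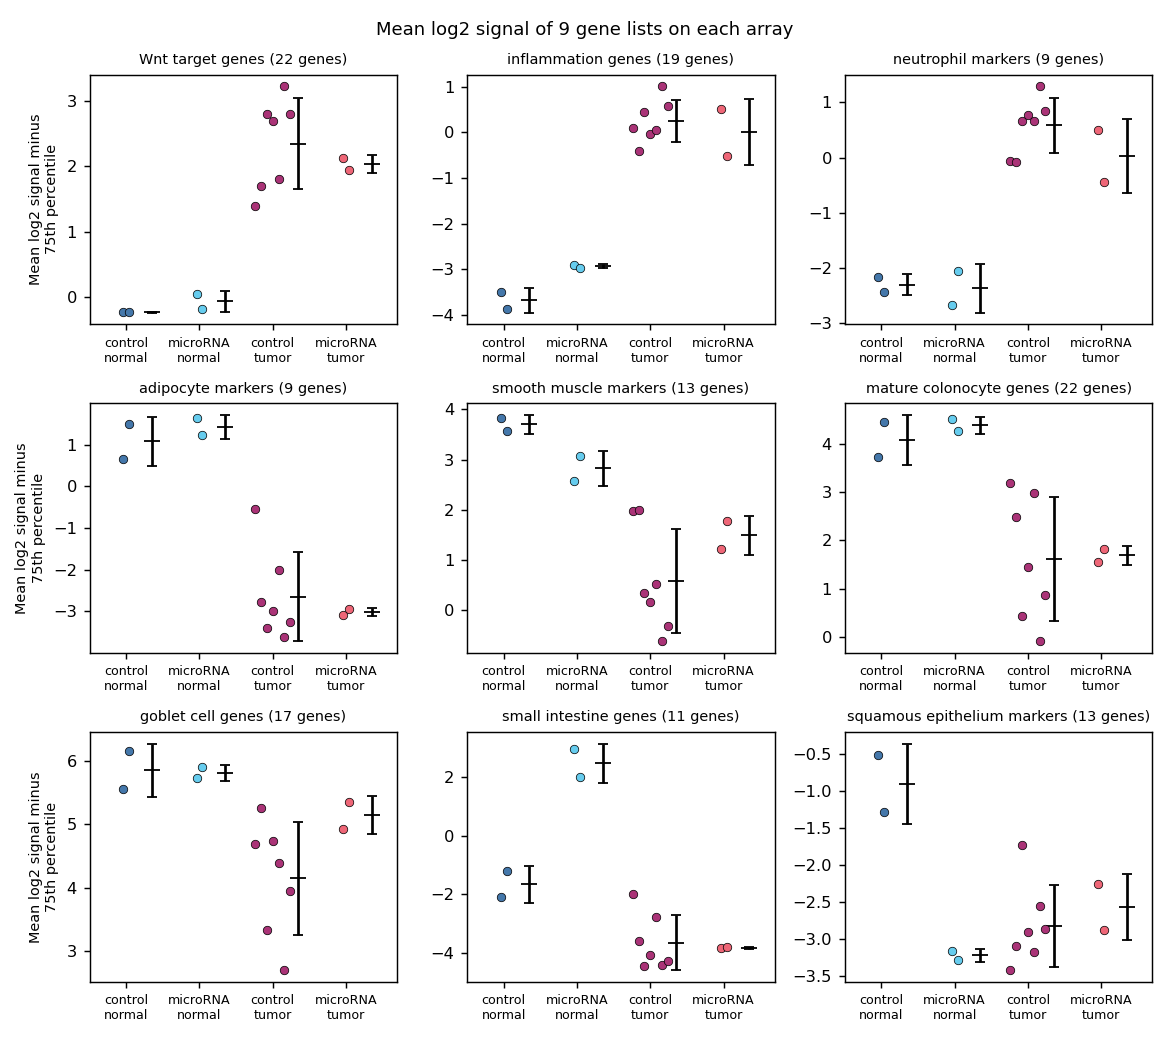
Mean log2 signal minus the array's 75th percentile for 9 gene lists. Each point is 1 array, and the bar beside each group is the mean ± SD (n = 2, 2, 7 and 2 from left to right). Wnt target genes lie between 1.39 and 3.24 in control tumors and at -0.23 and -0.24 in control normal tissue, and small intestine genes stand at 2.95 and 2.01 in normal tissue of microRNA mice alone.

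In control mice alone, the tumor effect was large at genes that led over both groups, which the choice of genes favors because that fit holds the same control arrays. Mmp10 rose by log2 8.37 (SE 0.72, adjusted p = 5.84e-05), from -4.44 ± 1.66 (SD, n = 2) in normal tissue to 3.93 ± 0.68 (SD, n = 7) in tumors. The complement regulator Cfi was at least 235-fold higher in tumors, the plasma protease Habp2 at least 219-fold, the proton channel Otop2 at least 169-fold, the hepatokine Lect2 at least 135-fold and Cxcl1 at least 78.7-fold. The antimicrobial α-defensins Defa4 (7.18) and Defa26 (6.56) rose, as did Onecut2 (7.14), and Il11 was at least 99.2-fold higher. Among the largest falls were several genes of skin and hair. Krt5 fell by 5.31 (SE 0.25, adjusted p = 1.93e-06), Krtdap by 6.62 and Flg by 6.74. The hair keratin associated genes Krtap22-2 and Krtap19-2 were at least 93.2-fold and 93.1-fold lower. The skeletal muscle myosin Myh8 was at least 120-fold lower and the calmodulin-like skin gene Calm4 at least 146-fold lower, while Cfd (-8.13) and Mptx1 (-7.73) fell. Celf5 fell by 6.97, but its probe was saturated on control normal 2, and its level in control normal tissue was 6.00 ± 7.36 (SD, n = 2).

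In this contrast 4867 genes changed, 2084 up and 2783 down, and 18 of the 32 lists were called, none of them with an estimated correlation (smallest adjusted p = 0.17 with an estimated correlation). Wnt target genes rose in 16 of 22 members, or 17 adjusted over the list alone (median 2.59, adjusted p = 2.74e-15, and adjusted p = 0.387 with an estimated correlation). Lgr5 rose by 2.59, Axin2 by 2.98 and Myc by 1.34, and Apc differed by 0.00 (adjusted p = 0.995). Inflammation genes rose in 17 of 19 members, or 18 adjusted over the list alone (median 4.16, adjusted p = 1.45e-35, and adjusted p = 0.17 with an estimated correlation). Paneth cell genes rose in 4 of 6 members and fell in 1, the same numbers when adjusted over the list alone (median 3.45, adjusted p = 1.08e-06, and adjusted p = 0.387 with an estimated correlation). B cell markers fell in 9 of 11 members, also 9 when adjusted over the list alone (median -3.06, adjusted p = 4.89e-05, and adjusted p = 0.408 with an estimated correlation), with Cd79b at -3.82. Squamous epithelium markers were lower in all 13 members and fell in 4, also 4 when adjusted over the list alone (median -1.33, adjusted p = 1.74e-07, and adjusted p = 0.387 with an estimated correlation). Goblet cell genes fell in 4 of 17 members, also 4 when adjusted over the list alone (median -1.48, adjusted p = 0.00694, and adjusted p = 0.434 with an estimated correlation). Zeb1 fell by 0.92 (adjusted p = 0.0255) but stood at 0.14 without scaling between arrays; Zeb2 differed by -0.87 (adjusted p = 0.0508) and Cdkn1a by -0.73 (adjusted p = 0.0774).

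With the slide as a block 2328 genes changed in control mice and within slide 2, with 1 tumor against 2 normal arrays, 2715 did; slide 1 held no control normal array. Wnt target genes had medians of 2.86 and 3.05 in these fits, inflammation genes 4.60 and 4.64, and B cell markers -3.18 and -3.54. Goblet cell genes had -2.47 and -2.66, Paneth cell genes 4.05 and 3.92, and squamous epithelium markers -0.29 and -0.12, the last of which was not called. The calls for Axin2, Myc, Zeb1, Mptx1 and Celf5 ended with the slide as a block. The count fell to 426 without control normal 1, to 727 without control normal 2, to 2974 and 3146 without control tumors 7 and 4, and to 1166 without the 2 arrays with Xist signal. The share of changed genes that rose was 42.8%, against 53.1% with quantile normalization, 50.6% with median scaling, 20.8% with normexp correction and 96.1% without scaling. It was 65.5% without control normal 1. Of the 18 lists, 11 were called without the 2 arrays with Xist signal, 14 without control normal 2, 15 without control tumor 3 and at least 16 without any other array. Goblet cell genes were not called without control normal 2 (-1.19, adjusted p = 0.0942) or without both arrays with Xist signal (-1.08, adjusted p = 0.181).

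Tumors of microRNA mice were compared with normal tissue of microRNA mice. Among the largest rises were the matrix metalloproteinases Mmp10 (log2 6.67, SE 0.89, adjusted p = 0.0035), Mmp13 (5.84) and Mmp3 (5.26), the activin subunit Inhba (6.04), the imprinted transcript H19 (5.94) and Cxcl5 (5.66). Spp1 was at least 131-fold and the platelet chemokine Ppbp at least 38.4-fold higher. Among the largest falls were genes of small intestinal absorption. Apoa1, the main protein of high-density lipoprotein, went from 3.29 ± 1.28 (SD, n = 2) in normal tissue to -6.69 ± 0.02 (SD, n = 2) in tumors and was at least 914-fold lower (adjusted p = 8.87e-05). The disaccharidase Sis was at least 1085-fold, the cholesterol transporter Npc1l1 at least 280-fold and the amino acid transporter Slc6a19 at least 218-fold lower, and the ileal bile acid binding gene Fabp6 fell by 9.54. The α-defensins Defa38 (-9.43) and Defa39 (-9.28) fell too, and Cfd was at least 796-fold lower.

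In this contrast 791 genes changed, 353 up and 438 down, and 15 lists were called, none with an estimated correlation (smallest adjusted p = 0.0784 with an estimated correlation). Small intestine genes fell in 9 of 11 members, or 11 adjusted over the list alone (median -5.98, adjusted p = 2.42e-39, and adjusted p = 0.0784 with an estimated correlation). Inflammation genes rose in 13 of 19 members and fell in 1, or 16 and 1 when adjusted over the list alone (median 3.31, adjusted p = 2.44e-23, and adjusted p = 0.0784 with an estimated correlation). Wnt target genes rose in 4 of 22 members, or 17 adjusted over the list alone (median 1.88, adjusted p = 1.21e-13, and adjusted p = 0.172 with an estimated correlation). Dkk2 was at least 33.6-fold higher, and Lgr5 (2.42, adjusted p = 0.0594) and Axin2 (1.78, adjusted p = 0.204) were not called. Mesenchymal transition genes rose in 4 of 14 members, or 7 adjusted over the list alone (median 1.22, adjusted p = 1.07e-08, and adjusted p = 0.0784 with an estimated correlation), with Fn1 at 2.52 and Sparc at 1.63. T and NK cell markers fell in 4 of 16 members, or 11 adjusted over the list alone (median -1.40, adjusted p = 5.4e-07, and adjusted p = 0.118 with an estimated correlation). The granzyme Gzma fell by 7.92 and Cd8a was at least 26.4-fold lower. Interferon-stimulated genes were lower in 20 of 21 members and fell in 1, Irf7 (-3.09), or 4 adjusted over the list alone (median -1.26, adjusted p = 0.00201, and adjusted p = 0.384 with an estimated correlation). Cdkn1a fell by 1.48 on its brightest probe, and its 3 probes ran from -1.77 to -0.08.

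In microRNA mice 1640 genes changed with the slide as a block, 10 within slide 1 and 287 within slide 2, each slide holding 1 tumor and 1 normal array whose spread is taken from the other groups. The medians of small intestine genes within slides 1 and 2 were -5.54 and -6.30 and -5.98 with the block. In the same order they were 2.62, 3.38 and 3.31 for inflammation genes, 2.03, 2.05 and 1.88 for Wnt target genes, and for T and NK cell markers -1.53, -1.64 and -1.40. The count was 78 without microRNA tumor 1, 174 and 222 without microRNA normals 1 and 2, 314 without microRNA tumor 2, and 1791 without control tumors 1 and 5. The share of changed genes that rose was 44.6%, against 61.1% with quantile normalization, 63.5% with median scaling, 18.5% with normexp correction, 94.7% without scaling and 27.3% without a filter. It was 55.2% without microRNA normal 1 and 51.3% without microRNA tumor 2. Enteroendocrine genes were not called without microRNA normal 2 (-1.61) and endothelial markers not without microRNA tumor 2 (0.51), and the other 13 of the 15 lists were called without any 1 array.

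The tumor effects of the 2 groups of mice, which share no arrays, were compared directly. Across 25486 genes, which are not independent replicates, they had a Pearson correlation of 0.636 and a Spearman correlation of 0.640, and a Spearman correlation of 0.569 when the microRNA mice were taken from slide 1 and the control mice from slide 2. Of the 353 genes that rose in microRNA mice, 285 rose in control mice, where 28.9 would be shared by independent lists. Of the 438 that fell, 237 fell in control mice, where 47.8 would be shared. Calls in both groups of mice used the same estimate of each gene's spread, which alone can raise the number shared. The lists are thus not independent, and 28.9 and 47.8 are no valid baseline for the overlap. Only 5 of the 527 genes called in both went in opposite directions.

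**Figure D3:**
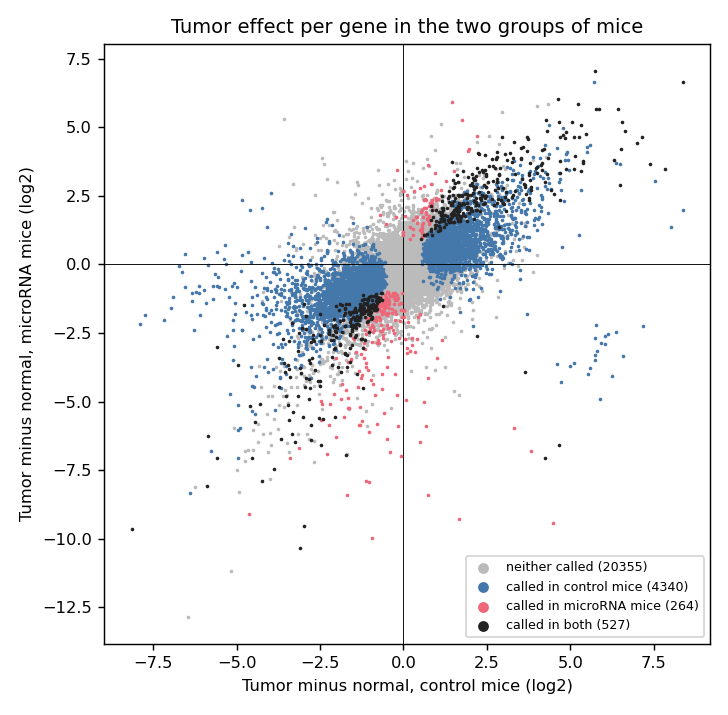
Tumor minus normal tissue (log2) of each of 25486 genes in control mice (horizontal axis) and in microRNA mice (vertical axis), with colors for genes called in neither, 1 or both. The 527 genes called in both lie along the diagonal, except 5 with opposite directions, and the Pearson correlation over all genes is 0.636.

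A test of the difference between the tumor effects called 72 genes, of which 26 had a higher and 46 a lower effect in microRNA mice. Among those with a lower effect were α-defensin genes, Defa38 (-13.92), Defa29 (-11.29), Defa42 (-11.25), Defa39 (-10.96), Defa5 (-10.31), Defa26 (-9.91) and Defa37 (-9.25), and Apoa1 at -9.04 (SE 0.88, adjusted p = 0.00197). Among those with a higher effect were the keratin genes Krt5 (5.32, SE 0.40, adjusted p = 0.000422), Krt1 (5.34), the hair gene Krtap19-2 (6.92) and the skeletal muscle myosins Myh8 (5.72) and Myh2 (5.196). Several of these genes were not well above background in 1 or more of the 4 groups: Krt1 and Krtap19-2 only stood above it in control normal tissue, Apoa1 only in normal tissue of microRNA mice, Krt5 did not in the latter and Defa39 not in control normal tissue. Their values rest on the background there, and their size is neither a measured difference nor a limit. Of 11 small intestine genes 3 were called, or 8 adjusted over the list alone (median -4.26, adjusted p = 7.24e-30, and adjusted p = 0.0657 with an estimated correlation). Of 13 squamous epithelium markers 2 were called, or 5 adjusted over the list alone (median 2.35, adjusted p = 1.32e-17, and adjusted p = 0.0657 with an estimated correlation). Between normal tissues of the 2 groups of mice 136 genes were called, and between their tumors 1. Small intestine genes had mean levels of 2.48 in normal tissue of microRNA mice and -1.66 in that of control mice. In tumors these were -3.83 and -3.66. Squamous epithelium markers had -3.22 and -0.90 in normal tissue, and -2.57 and -2.82 in tumors. For these 2 lists the difference thus lay mostly between the normal tissues. Wnt target genes were not called (median -0.26, adjusted p = 0.368, and adjusted p = 0.788 with an estimated correlation). At the preset correlation they were lower within slide 2 (median -0.91, adjusted p = 0.000329) and without control tumors 1 and 5 (-0.50, adjusted p = 0.0057), and higher with the replicate number as a block (0.39, adjusted p = 0.0443). With an estimated correlation none of these 3 passed (adjusted p = 0.713, 0.636 and 0.556).

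The slide as a block again gave 72 genes, and within slide 2 alone 16 did, all of them lower in microRNA mice; slide 1 could not be tested without a control normal array. Small intestine genes had medians of -4.10 and -3.66 in these fits and squamous epithelium markers 1.07 and 1.40. Of the 14 lists called, 9 were called without microRNA tumor 2, 11 without control normal 1, 11 without microRNA normal 1 and 12 without control tumor 3. Without control tumor 1, small intestine genes and mesenchymal transition genes were called also with an estimated correlation (both adjusted p = 0.0241). The count was 18 and 39 without microRNA normals 1 and 2, 21 and 35 without microRNA tumors 1 and 2, 32 without control normal 1, and 46 and 47 without control tumors 4 and 6. The share with a higher effect was 36.1%, against 47.6% with quantile normalization, 48.2% with median scaling and 12.2% with normexp correction. It was 62.5% and 64% without control normals 1 and 2, 56.3% without the 2 arrays with Xist signal and 52.4% without microRNA tumor 1. Without control normal 1, 20 genes with a higher and 12 with a lower effect were called.

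Tumors of microRNA mice were compared with tumors of control mice, to see what the treatment changed in the disease. No Wnt target, stem cell or proliferation gene was called. The stem cell receptor Lgr5 stood at 2.53 ± 0.48 (SD, n = 2) with the microRNAs and at 2.33 ± 0.80 (SD, n = 7) without. The Wnt feedback gene Axin2 stood at 0.98 ± 0.07 (SD, n = 2) and 1.55 ± 1.05 (SD, n = 7), and the proliferation marker Mki67 at 4.68 ± 0.34 (SD, n = 2) and 4.55 ± 0.23 (SD, n = 7). The reported miR-200c targets Zeb1 (log2 difference 0.41) and Zeb2 (0.25), which repress epithelial genes, and the reported miR-302 targets Cdkn1a (-0.33) and Ccnd1 (0.09) were not called. Neither were Myc (-0.18), Cd44 (0.07), Apc (0.18) and Cdx2 (-0.53), each with an adjusted p of 1. The only gene called was the olfactory receptor gene Olfr1055, at -3.99 ± 0.83 (SD, n = 2) against -6.64 ± 0.17 (SD, n = 7), at least 6.12-fold higher (adjusted p = 0.0428), with a probe on chromosome 2 from 86186983 to 86187042. Its call was made in 1 of the 13 fits that left out an array, and the count was 1 with the slide as a block, 3 within slide 1 and 0 within slide 2. The count was also 0 with the file-name number as a random block, with the replicate number as a block, in a fit to the 2 groups alone, with trend and robust estimation, with normexp correction and without scaling.

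The unadjusted p was under 0.05 at 537 genes between tumors, where chance alone gives 1274.3. Next in order, as values that did not pass, were Atp6ap1l, at least 3.53-fold higher (adjusted p = 0.506), and Wfdc12 (4.16). On the lower side were Art5, at least 2.61-fold lower, Mug1, at least 9.84-fold lower, and Bpifb5 (-4.78). Of 50 simulated genes with a log2 difference of 2 between these groups, 70% were called, and 18% of those with a difference of 1. For a difference of 2, 40% were called between normal tissues and 22% for the difference of the tumor effects. The simulated noise was independent, with 1 spread per gene and no slide or shared animal, so these shares may not hold for the real arrays.

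No member of any list was called between tumors, but 6 lists were called by camera, none with an estimated correlation (smallest adjusted p = 0.743 with an estimated correlation) or by fry. Goblet cell genes were higher in 16 of 17 members (median 0.88, adjusted p = 1.1e-07, and adjusted p = 0.743 with an estimated correlation), with the secretory chaperone Agr2 at 1.18 and Muc2 at 0.91. Smooth muscle markers were higher in 12 of 13 (median 1.16, adjusted p = 1.09e-05, and adjusted p = 0.743 with an estimated correlation), with Cnn1 at 1.96 and Actg2 at 1.16. Plasma cell markers were higher in all 9 members (median 0.54, adjusted p = 0.00196, and adjusted p = 0.743 with an estimated correlation), with Mzb1 at 0.94. Fibroblast markers were higher in 11 of 13 (median 0.42, adjusted p = 0.00156, and adjusted p = 0.743 with an estimated correlation), with Dcn at 0.63. B cell markers were higher in 10 of 11 (median 0.96, adjusted p = 0.00436, and adjusted p = 0.85 with an estimated correlation). Neutrophil markers were lower in 8 of 9 members, 1 of which fell when adjusted over the list alone (median -0.37, adjusted p = 0.0184, and adjusted p = 0.743 with an estimated correlation). Mmp9 stood at -1.64, S100a8 at -1.18 and S100a9 at -1.09, all 3 not called. The other 5 lists had 0 members called when adjusted over the list alone. Reported miR-200c targets (median 0.12, adjusted p = 0.132), reported miR-302 targets (0.03, adjusted p = 0.759), Wnt target genes (-0.18, adjusted p = 0.117), proliferation genes (0.08, adjusted p = 0.665) and mesenchymal transition genes (0.18, adjusted p = 0.179) were not called. At the preset correlation Wnt target genes were lower with the slide as a block (-0.38), within slide 2 (-0.60), with normexp correction (-0.19), without control tumors 1 and 5 (-0.48) and without control tumor 1 (-0.33), 2 (-0.29) or 5 (-0.22) or microRNA tumor 1 (-0.42). They were higher with the replicate number as a block (0.45). With an estimated correlation none of these passed (adjusted p = 0.589 to 0.871). Proliferation genes were lower within slide 1 (-0.22) and without microRNA tumor 1 (-0.23), and higher without microRNA tumor 2 (0.36) and with the replicate number as a block (0.39), at the preset correlation.

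With the slide as a block, within slide 1 and within slide 2, the medians between tumors were 1.16, 1.02 and 1.73 for goblet cell genes, 1.28, 1.22 and 1.04 for smooth muscle markers, and 0.52, 0.32 and 0.58 for plasma cell markers. They were 0.37, 0.35 and 0.13 for fibroblast markers, 1.06, 1.00 and 0.88 for B cell markers and -0.49, -1.06 and 0.04 for neutrophil markers. The calls for plasma cell and fibroblast markers ended within slide 1 and that for neutrophil markers within slide 2. Without control tumor 3, or without both arrays with Xist signal, the B cell (0.87) and neutrophil (-0.37) lists were no longer called. Without microRNA tumor 1 plasma cell markers (0.35) were not. Without microRNA tumor 2 the calls were kept for goblet cell genes (0.77, adjusted p = 0.0431) and fibroblast markers (0.49, adjusted p = 0.0392) and lost for smooth muscle (0.77), plasma cell (0.49), B cell (0.23) and neutrophil (0.02) markers. With the replicate number as a block, which leaves control tumors 1 and 2 alone to compare and does not pair the samples, none of the 6 calls was kept. Smooth muscle markers were then called in the opposite direction (-0.45, adjusted p = 0.0137), goblet cell genes stood at 0.39 (adjusted p = 0.302), fibroblast markers at 0.31, plasma cell markers at -0.03, B cell markers at -0.17 and neutrophil markers at 0.0783.

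Normal tissue of microRNA mice was then compared with normal tissue of control mice. Among the largest rises with the microRNAs were several α-defensins, antimicrobial peptides of Paneth cells. Defa38 stood at 7.19 ± 1.09 (SD, n = 2) against -4.78 ± 2.38 (SD, n = 2), a log2 difference of 11.97 (SE 1.81, adjusted p = 0.00985). Defa21 (10.49), Defa42 (10.47), Defa29 (10.31), Defa5 (9.75), Defa26 (9.72), Defa32 (8.97) and Defa37 (8.95) rose too, with Defa39 at least 530-fold higher. These genes are close relatives, and 1 probe can bind transcripts of several. Apoa1 (chromosome 9, 46037921 to 46037980) was at least 379-fold higher (adjusted p = 0.000214), Apoa4 at least 6.35-fold, and the lipoprotein assembly gene Mttp (4.90) and Fabp6 (6.89) rose. Several genes of skin and hair were among the largest falls. Krt5, a keratin of basal squamous cells (chromosome 15, 101537514 to 101537573), was at least 37.4-fold lower (adjusted p = 4.14e-05), Krtap19-2 at least 135-fold, Flg at least 86.8-fold and Krt1 at least 47.5-fold, and the cornified envelope gene Lor fell by 6.56.

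Between normal tissues 136 genes changed, 73 up and 63 down, and 12 lists were called, of which small intestine genes, squamous epithelium markers and mesenchymal transition genes were also called with an estimated correlation. Small intestine genes were higher in all 11 members and rose in 4, or 9 adjusted over the list alone (median 4.07, adjusted p = 2.7e-47, and adjusted p = 0.0336 with an estimated correlation). Squamous epithelium markers were lower in all 13 members and fell in 3, or 4 adjusted over the list alone (median -1.30, adjusted p = 1.4e-24, and adjusted p = 0.0336 with an estimated correlation). Mesenchymal transition genes were lower in all 14 members, none of which was called over all genes and 1 of which fell when adjusted over the list alone (median -0.74, adjusted p = 1.01e-06, and adjusted p = 0.0336 with an estimated correlation). Its member Zeb1 stood at -1.22 (adjusted p = 0.181), Zeb2 at -0.89 (adjusted p = 0.768) and Sparc at -0.62 (adjusted p = 0.912). Reported miR-200c targets, of which Zeb1 and Zeb2 are 2, were lower in 11 of 15 members, none of which was called over all genes and 3 of which fell when adjusted over the list alone (median -0.50, adjusted p = 0.000263, and adjusted p = 0.0501 with an estimated correlation). Another member, Msn, stood at -0.97 (adjusted p = 0.298). Reported miR-302 targets were not called (median -0.11, adjusted p = 0.225), and Cdkn1a differed by 0.42 (adjusted p = 0.959). Paneth cell genes rose in 2 of 6 members, or 4 adjusted over the list alone (median 2.07, adjusted p = 1.43e-09, and adjusted p = 0.0501 with an estimated correlation).

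Immune and stromal lists moved between normal tissues too. B cell markers were lower in 9 of 11 members (median -2.14, adjusted p = 7.4e-07, and adjusted p = 0.295 with an estimated correlation), with Cd79b at -2.52. Smooth muscle markers were lower in all 13 (median -0.87, adjusted p = 0.00223, and adjusted p = 0.5679 with an estimated correlation), with Acta2 at -0.85. No member of either was called, also when adjusted over the list alone. Fibroblast markers were lower in 12 of 13 members (median -0.62, adjusted p = 0.00132, and adjusted p = 0.225 with an estimated correlation) and endothelial markers in all 12 (median -0.43, adjusted p = 0.00121, and adjusted p = 0.115 with an estimated correlation), again with no member called by either adjustment. Interferon-stimulated genes were higher in 20 of 21 members (median 1.04, adjusted p = 7.05e-05, and adjusted p = 0.338 with an estimated correlation), none of them called by either adjustment, with Oasl2 at 1.45. Inflammation genes rose in 1 of 19 members, the nitric oxide synthase Nos2 (4.27, adjusted p = 0.00558), or 3 adjusted over the list alone (median 0.53, adjusted p = 0.000413, and adjusted p = 0.486 with an estimated correlation). T and NK cell markers were higher in 15 of 16 members, 2 of which rose when adjusted over the list alone (median 0.46, adjusted p = 0.0113, and adjusted p = 0.371 with an estimated correlation). Wnt target genes were not called (median 0.07, adjusted p = 0.937), with Lgr5 at 0.36, Axin2 at 0.64 and Apc at 0.14.

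The slide as a block gave 138 genes between normal tissues, and within slide 2, with 1 array against 2, 42 did, all of them higher with the microRNAs; the calls for Krt5, Krt1, Lor, Flg, Fabp6, Apoa4, Defa38 and Defa26 ended there. In these fits small intestine genes had medians of 3.67 and 4.74, squamous epithelium markers -1.08 and -1.60, and mesenchymal transition genes -0.60 and -0.58. Paneth cell genes had 2.43 and 2.67, B cell markers -2.22 and -1.88 and reported miR-200c targets -0.30 and -0.33, the last of which was not called. The count was 52 and 78 without microRNA normals 1 and 2 and 73 without control normal 1. The share of changed genes that rose was 53.7%, against 75% with normexp correction, 49.1% with quantile normalization and 83.6% in a fit to the 2 groups alone, and 42.5% without control normal 2. Without control normal 1 interferon-stimulated genes (0.60) and endothelial markers (-0.33) were not called. T and NK cell markers were not without control normal 2 (0.47) or microRNA normal 1 (0.34), nor smooth muscle markers without the latter (-0.69).

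Over both tissues together, adjusted for tissue, limma called 0 genes between microRNA and control mice, and 577 genes had an unadjusted p under 0.05, where chance alone gives 1274.3. Among the genes with the smallest p were Gramd2 (1.13) on the higher side and Tnnc2 (-2.65) and the gelatinase gene Mmp9 (-1.47) on the lower side, each with an adjusted p of 1. Of 50 simulated genes with a log2 difference of 2, 72% were called in this contrast, again with independent noise and no slide or shared animal. The slide as a block and slide 2 alone also gave 0 genes. Slide 1 alone gave 3, but there this contrast compares tumors only, for lack of a control normal array. Camera called 10 lists, none with an estimated correlation (smallest adjusted p = 0.481 with an estimated correlation) and none by fry. Small intestine genes were higher in all 11 members (median 1.28, adjusted p = 4.74e-10, and adjusted p = 0.481 with an estimated correlation), with no member called by either adjustment. Interferon-stimulated genes were higher in all 21 (median 0.40, adjusted p = 4.71e-06, and adjusted p = 0.481 with an estimated correlation), with no member called by either adjustment. Within slide 2 the medians were 2.87 for small intestine genes and 0.23 for interferon-stimulated genes, the last of which was not called, and with the slide as a block 1.31 and 0.39. Between the tumors of slide 1 they were -0.10 and 0.42. Of the 10 lists, 6 were called without microRNA normal 2 and 6 without microRNA tumor 2.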

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

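The tests of the slide for all 3 patterns below, of an effect common to normal and tumor tissue, of the control tumor with the lowest goblet cell genes and of other splits by treatment, and the look at Hoxb13, were chosen only after the results were seen.

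The group of 7 control tumors was large enough to look for single samples far from the others, and 8 of 128 genes and 0 of 26 lists had one by Dixon's ratio of the gap to the nearest sample over the whole range. Chance alone gives such a sample in about 1 in 20 groups. Control tumor 1 stood high for the adipocyte genes Adipoq (ratio 0.762, level -2.77 against -5.69 to -4.99) and Cfd (0.699, level 0.33 against -6.98 to -4.78) and for Apoa1 (0.764). Control tumor 5 stood high for the squamous genes Flg (0.769) and Krt71 (0.680) and control tumor 4 for Fn1 (0.607) and Slc6a19 (0.583). Apoa1 and Krt71 were not well above background in control tumors, so their ratios rest on the background. Control tumor 3 stood low for Tnnc2 (0.727).

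The tumor effect differed between microRNA and control mice, by a test of the difference itself, at 10 named genes with a higher and 14 with a lower effect in microRNA mice. Higher were Krtap19-2 (log2 6.92), Krtap22-2 (5.73), Myh8 (5.72), Krt33a (5.58), Krt1 (5.34), Krt5 (5.32), Crct1 (5.23), Myh2 (5.196), Krt71 (5.05) and Lce1a1 (4.91). Lower were Apoa4 (-3.27), Nos2 (-4.81), Mttp (-4.85), Apoa1 (-9.04), Slc6a19 (-9.12), Defa37 (-9.25), Defa-rs4 (-9.35), Defa26 (-9.91), Defa5 (-10.31), Bpifb5 (-10.79), Defa39 (-10.96), Defa42 (-11.25), Defa29 (-11.29) and Defa38 (-13.92). Krtap19-2, Krtap22-2, Krt33a, Krt1, Crct1, Krt71 and Lce1a1 stood well above background in control normal tissue only, and Apoa1 and Apoa4 in normal tissue of microRNA mice only. Krt5, Myh2, Myh8, Slc6a19, Defa39 and Bpifb5 did not in 1 or more groups. The values of all these genes rest on the background there, and their size is neither a measured difference nor a limit. The calls for Krt1, Crct1, Bpifb5, Slc6a19 and Nos2 ended with the slide as a block. A difference of tumor effects also takes in the difference between the normal tissues, where 136 genes were called. Between tumors the only call was Olfr1055, so none of the genes named here was called there.

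The same test by camera called 14 lists. The tumor effect was higher in microRNA mice for B cell markers (median 3.32), squamous epithelium markers (2.35), smooth muscle markers (2.16), enteric neuron and glia markers (1.23), fibroblast markers (1.14), goblet cell genes (0.96), mesenchymal transition genes (0.83), reported miR-200c targets (0.54) and endothelial markers (0.49). It was lower for small intestine genes (-4.26), Paneth cell genes (-2.11), interferon-stimulated genes (-0.87), inflammation genes (-0.72) and T and NK cell markers (-0.65). For small intestine genes and squamous epithelium markers the difference lay mostly between the normal tissues of the groups of mice. No list was called with an estimated correlation, where the smallest adjusted p was 0.0657, but small intestine and mesenchymal transition genes were without control tumor 1 (both adjusted p = 0.0241). All 14 were called with the slide as a block and 12 within slide 2, where endothelial markers and reported miR-200c targets were not.

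Small intestine genes were higher in normal tissue of microRNA mice than of control mice. The slide alone does not explain this, because the median difference was 4.74 within slide 2. Between tumors the median was -0.0520. The list was low there, with means of -3.83 in tumors of microRNA mice and -3.66 in control tumors. Its members Apoa1 and Apoa4 were not well above background in tumors. The value between tumors therefore does not decide about an effect of the microRNAs common to both tissues. A candidate source is a piece of small intestine in the normal samples of microRNA mice: 9 of 10 other small intestine genes, none of them in the lists of the report, were higher there (median 2.48), although 1 was called, Slc7a9 (4.70, adjusted p = 0.0349). The medians of these genes were 4.03 and 3.08 in normal tissue of microRNA mice and 0.34 and 0.27 in that of control mice, and the most abundant in normal tissue of microRNA mice, Mep1b, stood at 6.30 against 3.87, but 5 of the 10 also lay above the 75th percentile in control normal tissue. An effect of the microRNAs on normal tissue alone stays open as well, and so does another site along the gut, which no label states: the distal gene Hoxb13 stood at 5.65 and -0.50 in normal tissue of microRNA mice and at 6.35 and 5.90 in that of control mice, so it was low in 1 of the 2 arrays with high small intestine genes.

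Squamous epithelium markers were higher in normal tissue of control mice than of microRNA mice. The slide alone does not explain this list, with a median of -1.60 within slide 2, although no named skin gene was called there. A candidate source is anal skin and muscle in the control normal samples: 6 of 8 skeletal muscle genes were lower in microRNA mice (median -0.79), but the range of -2.35 to 0.83 leaves this open. The hair genes Krtap19-2, Krtap22-2, Krt33a and Krt71 were well above background in control normal tissue only. The skeletal muscle myosins Myh8 (5.72) and Myh2 (5.196) were called for the difference of the tumor effects. Both go with this source, but these genes were named for their large differences and are no separate test. Of the 13 squamous markers, 5 lay above the 75th percentile in control normal tissue and 3 in that of microRNA mice. A true difference between the mice stays open.

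Goblet cell genes were higher in tumors of microRNA mice than in control tumors. The slide alone does not explain the difference, with a median of 1.16 with the slide as a block. Nor does 1 control tumor with low levels of these genes. The median was 0.66 without control tumor 6, which had the lowest mean (2.70), and 0.86 without control tumor 3, which had the next (3.33). Several low control tumors together were not tested. The groups overlap, with means of 4.93 and 5.36 in microRNA tumors 1 and 2 and 5.26 in control tumor 2. An effect of the microRNAs stays open, as does a differing share of goblet cells among tumors for any other reason, with an adjusted p of 0.743 with an estimated correlation. With the replicate number as a block the list was not called (0.39, adjusted p = 0.302). Smooth muscle (median 1.16), B cell (0.96), plasma cell (0.54) and fibroblast (0.42) markers were also higher between these tumors and neutrophil markers lower (-0.37), none of them called with an estimated correlation (smallest adjusted p = 0.743) or in the same direction with that block, where smooth muscle markers were called lower (-0.45, adjusted p = 0.0137) and B cell markers stood at -0.17; a differing mix of several cell types was not tested and stays open too.

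Other splits of the 13 arrays into groups of 4 and 9 were fitted for the counts over both tissues or both groups of mice. For tumor against normal tissue 1 of 100 splits, the real one, gave as many as 7994 genes, with 4637 as the highest other. That other split held 3 of the 4 normal arrays in its smaller group, all from slide 2. The real count was thus the highest of the splits fitted. With 100 splits of arrays that may share animals, this does not exclude chance. The splits ignored the slides and any shared animal, and arrays that share a number in their file names had a correlation of 0.347; the count was 8437 with the slide as a block and 4894 within slide 2. For treatment the real count was 0, which each of the 100 splits must reach, so that test decides nothing; the highest other was 5.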

How the results depend on the processing

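Leaving out control tumors 1 and 5 and leaving out the 2 arrays with Xist signal were chosen only after the data were seen, as were list tests that join an estimated correlation with another setting. Of 204 counts of changed genes under the alternatives, 130 stayed within 1.5 times the count in the report. Of 2762 results of lists called in the report 2482 kept direction and side of the threshold, 271 were no longer called and 9 reversed. Of 5877 named gene results 5310 kept their side of the threshold, 537 were no longer called and 28 were newly called. The other 2 reversed, with a call in at least 1 of the 2 fits compared. A change of sign at a gene called in neither fit was counted as kept. The cause was not tested for the changes below, except where fewer arrays or an added threshold account for them.

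Normexp correction gave 12250 genes changed between tumor and normal tissue over both groups of mice, 8489 in control mice and 2477 in microRNA mice, 0 between tumors, 76 between normal tissues and 41 for the difference of the tumor effects. Without scaling between arrays the tumor effect called 15313 genes, 95.5% of them higher, with 12586 in control and 3069 in microRNA mice, and 0 genes were called between tumors. Without a filter on dim probes 13015 genes were called over both groups, 1558 in microRNA mice and 2 between tumors. An added 2-fold threshold left 4722 over both groups. A fit to the compared groups alone called 0 genes between tumors and 55 between normal tissues, and eBayes with trend and robust estimation 0 between tumors. The slide as a block gave 2328 genes in control and 1640 in microRNA mice. Within slide 1, with fewer arrays and no control normal array, 10 genes were called for the tumor effect in microRNA mice and 3 between tumors. The models over both groups or both tissues come down to these comparisons there and gave 10 and 3 again, so they have no value of their own within slide 1. Within slide 2, with fewer arrays, the tumor effect called 4894, 2715 in control and 287 in microRNA mice, with 0 between tumors, 42 between normal tissues and 16 for the difference. The file-name number as a random block gave 2310 in microRNA mice and 0 between tumors. The replicate number as a block gave 2828, 449 in control and 1223 in microRNA mice, 0 between tumors, 63 between normal tissues, 12 for the difference and 0 between microRNA and control mice over both tissues. Without control tumors 1 and 5, 1791 genes were called in microRNA mice and 0 between tumors. Without the 2 arrays with Xist signal 4150 were called over both groups, 1166 in control mice and 0 between tumors. Quantile normalization, median scaling, the filter by group and the mean of all probes moved no count by more than 1.5 times. The all-gene median of the tumor effect was -0.27 with normexp, 0.89 unscaled and -0.34 without the filter.

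Leaving out 1 array at a time gave 3842 to 8669 genes between tumor and normal tissue over both groups of mice, 426 to 6725 in control mice and 78 to 1162 in microRNA mice. It gave 0 to 1 between tumors, 52 to 157 between normal tissues, 18 to 93 for the difference of the tumor effects and 0 to 0 between microRNA and control mice over both tissues. Where this left 1 sample in a group, that sample was assumed to vary like the other groups.

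Reversals were counted for lists called in the report and for named genes called in the report or under the alternative. Among these, the direction of a gene, or of the test of a list, reversed under 3 alternatives. Lists not called in the report were left out of this count. Wnt target and proliferation genes between tumors were such lists, and alternatives given above called them in either direction. Within slide 1 the tumor effect, there of microRNA mice alone, was 0.44 for Mptx1 and 0.34 for B cell markers. The difference between microRNA and control mice, there of tumors alone, was 0.14 for mesenchymal transition genes, 0.13 for endothelial markers, 0.12 for squamous epithelium markers and -0.10 for small intestine genes. These are other quantities than those over both groups or tissues. With the replicate number as a block, plasma cell markers over both tissues kept a median of 0.10 while the test turned, and between tumors B cell markers came to -0.17, neutrophil markers to 0.0783 and smooth muscle markers to -0.45 (adjusted p = 0.0137). Without scaling between arrays, Zeb1 in control mice came to 0.14. Medians alone turned, with the direction of the test kept, for oxidative phosphorylation genes over both groups (0.13) and in control mice (0.32) and for T and NK cell markers in control mice (0.14) without scaling. Between tumors they did so for neutrophil markers within slide 2 (0.04) and without microRNA tumor 2 (0.02), and for plasma cell markers with the replicate number as a block (-0.03). Between microRNA and control mice over both tissues they did so for Paneth cell genes within slide 1 (-0.10) and neutrophil markers without microRNA tumor 2 (0.03), and for the tumor effect over both groups for fibroblast markers without microRNA tumor 1 (-0.03). With the replicate number as a block none of the 6 list calls between tumors was kept.

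Slide 1 held no control normal array, so control mice, normal tissues and the difference of the tumor effects have no value there. A fit to the compared groups alone does not apply to the models over both tissues or to that difference. Signal near background limits the folds given as at least and the sizes of many differences of the tumor effects, and 50.7% to 57.0% of probes were well above background on each array.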

Other observations

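The values of Xist, Ddx3y and the Hox genes by array were looked up only after the data were seen.

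Xist, which is transcribed from the inactive X chromosome of female cells, stood at 0.45 in control normal 2 and 1.97 in control tumor 3, and at or below -5.80 on the other arrays. The Y-linked helicase Ddx3y stood at -6.42 and -6.81 on these 2 arrays and at 0.11 to 1.01 on the others. Both arrays are from slide 2 and share a number in their file names. No label gives the sex of the animals.

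Hoxb13, a gene of the distal hindgut, stood at -1.57 in control tumor 1, -4.53 in control tumor 5 and -0.50 in microRNA normal 2, and at 5.65 to 6.63 on the other arrays. Hoxd13 stood at -6.40 and -6.69 in control tumors 1 and 5, at -6.02 in microRNA normal 2, at -6.23 in control tumor 4 and at -3.10 in microRNA tumor 2. Hoxa13 stood at -4.76 and -3.73 in control tumors 1 and 5. The distal Hox list did not differ between tumors (median 0.19, adjusted p = 0.602), where its mean and test had the opposite sign, and had a median of -0.79 between normal tissues (adjusted p = 0.0593). Its median over both tissues was -0.60 (adjusted p = 0.0201, and adjusted p = 0.481 with an estimated correlation).

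Deviations of arrays with the same replicate number from their group means had a correlation of 0.42 between normal tissue and tumors of microRNA mice and of -0.14 and -0.10 in control mice. In microRNA mice these arrays also share a slide and a file-name number, and with 2 arrays per group this is a single mirrored value, so it does not show pairs. Across treatments the correlation was -0.15 for replicate 1 and 0.33 for replicate 2 between tumors, and -0.02 between normal tissues. The consensus correlation of arrays that share a number in their file names was 0.347 with the additive model and 0.303 with 4 group means.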
